A study of Mus musculus with 9 samples.

How the data were processed

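Polyadenylated RNA of MH-S cells, a mouse alveolar macrophage line transformed with SV40, was sequenced in 9 libraries, 3 from controls, 3 from cells given 20 µg/ml copper oxide nanoparticles (CuO NPs) and 3 from cells given 20 µg/ml CuO NPs with 10 µM TTM, all taken at 24 h. The labels do not spell TTM out, and in copper research the letters usually stand for tetrathiomolybdate, a copper chelator. The libraries were made with a stranded poly(A) mRNA kit and sequenced in pairs of reads. The authors deposited gene values in TPM, transcript abundances scaled for length to 1 fixed total per library, written with 2 decimals, for 56980 Ensembl gene identifiers. Per the submitters' processing notes, fastp, HISAT2, RSEM and DESeq2 were used with the mouse build GRCm39, without versions or the role of each tool. Every column of the deposited TPM table summed to the same total within rounding. TPM values keep no record of the number of reads, and no counts were used here, so the depth per library is unknown and no counting interval was given. Whether reads were counted by strand is not stated, so values of genes that overlap on opposite strands are uncertain.

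Gene symbols came from a reference annotation matched by Ensembl identifier, which paired 52073 of the 56980 identifiers, and 348 of the genes tested had no symbol. That annotation is for another mouse build than GRCm39, so no coordinates were given. The table pairs genes with no annotation terms, so the planned test of such terms was not run. Marker lists written with older or newer symbols were matched through the annotation, and 1 of the listed histone genes, H4c12, had no match.

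Genes were tested when TPM was at least 1 in at least 3 of the 9 libraries, which left 12904 genes. All libraries entered 1 fit of log2(TPM + 1) with a mean per group (limma 3.58.1 in R 4.3.3, lmFit, contrasts.fit and eBayes with an intensity trend, two-sided). The 3 comparisons were CuO NPs against control, CuO NPs + TTM against CuO NPs, and CuO NPs + TTM against control. P-values were adjusted by Benjamini-Hochberg within each comparison and a gene was called at an adjusted p below 0.05. Log2 fold changes are on the scale of log2(TPM + 1), which shrinks those of genes with few TPM, and TPM levels are given as mean ± SD. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

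Before the data were examined, 34 gene lists were fixed. They covered metallothioneins and zinc export, copper handling, cuproptosis and lipoylation, iron-sulfur cluster assembly, targets of NRF2, heat shock factor 1, ATF4 and CHOP, p53, SREBP2, LXR and HIF-1, chaperones of the endoplasmic reticulum, proteasome subunits, inflammatory and interferon-stimulated genes, antigen presentation, lysosome, autophagy, ferroptosis, DNA replication and mitosis, the respiratory chain, the tricarboxylic acid cycle, alveolar macrophage identity, macrophage core genes, immediate early genes and ribosome biogenesis. They also covered markers of fibroblasts, epithelium, endothelium, lymphocytes and granulocytes, mitochondrially encoded mRNAs, cytosolic ribosomal proteins and replication-dependent histones. A gene on more than 1 list was counted under each. The 30 lists with at least 3 tested members were compared with all other genes by camera in limma with an inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with a correlation estimated per list. With an estimated correlation camera also takes p from a t distribution with fewer degrees of freedom, set by the libraries and not the genes.

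The rule for genes named in the text was also fixed before the data were examined. It took per comparison the 8 highest and 8 lowest log2 fold changes among called genes whose groups did not overlap, with a mean of at least 5 TPM in either group and without predicted-gene names. It added up to 3 called members of each list with the largest changes, or the member with the highest mean TPM where none was called, and in every comparison Mt1, Mt2, Hmox1, Slc31a1, Atp7a, Fdx1, Dlat and Lias. Members of a list outside this rule were named only because a count was 5 or fewer, so they were chosen after their values were seen. The members called in 1 list for CuO NPs + TTM against CuO NPs, and those called in 1 list for CuO NPs against control with median-of-ratios scaling, are not reported here.

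The reversal of CuO NP changes was measured over the genes called in CuO NPs against control. It counted those called in the opposite direction with TTM, and took the median over genes of the difference from control with TTM divided by that without it. After the results were seen, that median was also taken with separate control libraries for the 2 differences, and over as many genes of lowest p in 50 simulations of unchanged groups. Both comparisons share libraries, so covariances were set beside those of 50 simulations of unchanged groups that share libraries in the same way.

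The fit was tested on simulated data made from these libraries with known changes added to genes drawn at random among those above about 5 TPM. It recovered 65.7% to 68.7% of log2 changes of 0.5 and at least 97.0% of changes of 1, and 2.82% to 8.93% of its calls were false. Only a small part of the genes was changed there, with noise independent between genes and no shift of whole libraries. These shares therefore need not hold for genes of lower level or for the real comparisons. Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, TPM recomputed without mitochondrially encoded genes, only the 2 groups compared, no intensity trend, robust eBayes, the estimated correlation, and each library left out in turn. A scaling without mitochondrial genes, the predicted genes that repeat them, and ferritin, and a centring of each library on its median gene, were added after the data had been seen. Other splits of the libraries and tests of technical explanations were also run.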

Results

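RNA levels were measured at 24 h in MH-S cells, a mouse alveolar macrophage line, in 3 groups of 3 libraries each. The groups were controls, cells given 20 µg/ml CuO NPs, and cells given 20 µg/ml CuO NPs with 10 µM TTM. No group received TTM alone, so TTM was measured only beside the nanoparticles. Between 19710 and 20863 genes per library had a value above 0, and the sequencing depth behind them is unknown. Across genes, Pearson correlations of log2(TPM + 1) were 0.981 to 0.986 between libraries of 1 group and 0.943 to 0.962 between groups, and genes are not independent replicates. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

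The comparison of CuO NPs with control asked which transcripts differed after exposure to the nanoparticles. Most NRF2 targets, heat shock factor 1 targets and genes of the integrated stress response were higher, and most macrophage core genes were lower. Camera called 14 of 30 lists, and with an estimated correlation the macrophage core genes were the only list called. Mt2 (ENSMUSG00000031762), which encodes a metallothionein, a small protein that binds copper and zinc, rose from 328 ± 10.5 TPM to 1869 ± 74.1 TPM (SD, n = 3 per group, as for all levels given). Hspa1a (ENSMUSG00000091971), which encodes an inducible heat shock protein, rose from 2.36 ± 0.426 TPM to 338 ± 8.32 TPM, and Hmox1 (ENSMUSG00000005413), which encodes the haem-degrading enzyme haem oxygenase 1, rose from 1037 ± 44.1 TPM to 5165 ± 124 TPM. C1qb (ENSMUSG00000036905), which encodes a subunit of complement C1q, fell from 35.0 ± 4.25 TPM to 2.28 ± 0.187 TPM. For these 4 genes, all 3 libraries of a group lay on the same side of all 3 of the other group. The rule for naming the largest changes required this, so it adds no support for Hspa1a and C1qb.

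Of the 4 tested metallothionein and zinc-export genes, 3 rose (3 adjusted over the list alone), with a camera adjusted p = 1.75e-05 and an adjusted p = 0.0952 with an estimated correlation. They were Mt2 with a log2 fold change of 2.51 (SE 0.065, limma adjusted p = 1.45e-08), Mt1 (ENSMUSG00000031765), which rose from 652 ± 22.8 TPM to 3243 ± 133 TPM, and the zinc exporter Slc30a1, which rose from 2.93 ± 0.061 TPM to 12.05 ± 0.395 TPM. Mtf1, the metal-responsive transcription factor, had a log2 fold change of 0.02. Among 17 copper-handling genes, 4 rose and 7 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.667). The median of that list was -0.22, or -0.10 relative to the median of all genes, and its mean was -0.10, while the sign of the test was positive. With median-of-ratios scaling 6 of them rose and 4 fell, Slc31a1, Sco1, Slc31a2 and Atp7a, so the balance of this list depends on the scaling. With TPM scaling those that rose were Cp with 0.49, Cox17 with 0.43, Sod1 with 0.40 and Atox1 with 0.34. Atp7a, a copper-exporting ATPase, fell from 17.3 ± 2.11 TPM to 9.94 ± 1.39 TPM. Slc31a1, the copper importer, fell from 58.0 ± 2.07 TPM to 46.7 ± 1.51 TPM, and its call was lost when each library was centred on its median gene (log2 fold change -0.13). Of 18 genes of cuproptosis and protein lipoylation, 9 fell (9 adjusted over the list alone, camera adjusted p = 0.160, median -0.19, or -0.07 relative to the median of all genes), among them Dbt, a subunit of the branched-chain ketoacid dehydrogenase, from 24.9 ± 1.79 TPM to 13.6 ± 2.07 TPM. Fewer of that list fell with median-of-ratios scaling, and with no filter the list had an adjusted p = 0.00852, within a range of 0.00852 to 0.593 over all alternatives. Fdx1 and Dlat had log2 fold changes of 0.04 and -0.07. Lias had 0.11, and with median-of-ratios scaling 0.24, which passed the test.

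Of 37 NRF2 targets, 26 rose and 4 fell (26 and 5 adjusted over the list alone, camera adjusted p = 1.39e-14, adjusted p = 0.0509 with an estimated correlation). Nqo1, a quinone reductase, rose from 0.867 ± 0.227 TPM to 5.06 ± 1.499 TPM, and the glycine transporter Slc6a9 from 11.2 ± 0.135 TPM to 46.2 ± 4.59 TPM. The 4 that fell were Cbr1 with -0.23, Blvra with -0.24, Tkt with -0.33 and the fatty acid transporter Cd36 with -1.19. Of 25 heat shock factor 1 targets and chaperones, 18 rose and 2 fell, Hspd1 with -0.15 and Hspa4 with -0.26 (18 and 2 adjusted over the list alone, camera adjusted p = 3.68e-15, adjusted p = 0.0869 with an estimated correlation). Dnajb1, a co-chaperone of Hsp70, rose from 17.8 ± 1.49 TPM to 150.4 ± 2.63 TPM. Hspa1b, which rose from 1.20 ± 0.246 TPM to 186 ± 11.2 TPM, is nearly identical in sequence to Hspa1a, so the division of reads between them is uncertain. Of 33 targets of the integrated stress response, 27 rose and 1 fell, Atf5 with -0.95 (28 and 1 adjusted over the list alone, camera adjusted p = 1.10e-19, adjusted p = 0.0509 with an estimated correlation). Trib3, a pseudokinase induced by ATF4 and CHOP, rose from 20.6 ± 0.482 TPM to 74.6 ± 5.19 TPM, and Ddit3, which encodes CHOP, from 33.0 ± 2.10 TPM to 87.3 ± 5.94 TPM. Of 24 chaperones of the endoplasmic reticulum, 4 rose, Dnajb9, Hyou1, Herpud1 and Derl1, and 5 fell, Hsp90b1, Ero1a, P4hb, Selenos and Edem1 (4 and 5 adjusted over the list alone, camera adjusted p = 0.313). Their median was -0.06, their mean 0.02 and the sign of the test positive, and the median was above 0 under 4 of 5 other scalings. With median-of-ratios scaling 10 of them rose and 3 fell, P4hb, Selenos and Edem1. Of 31 proteasome subunits, 15 rose and 2 fell, Psma6 with -0.19 and Psmd6 with -0.21 (15 and 2 adjusted over the list alone, camera adjusted p = 4.11e-07, adjusted p = 0.173 with an estimated correlation), while 25 rose and none fell with median-of-ratios scaling. Psmb3, a subunit of the 20S core, rose from 248 ± 11.4 TPM to 352 ± 8.40 TPM. Of 28 autophagy genes, 12 rose and 5 fell, Atg3, Bnip3, Ulk2, Bnip3l and Atg4b (12 and 5 adjusted over the list alone, camera adjusted p = 5.84e-04, adjusted p = 0.102 with an estimated correlation). Sqstm1, an autophagy receptor that is also on the NRF2 list, rose from 279 ± 6.66 TPM to 851 ± 35.2 TPM. Of 26 p53 targets, 9 rose and 8 fell (10 and 8 adjusted over the list alone, camera adjusted p = 0.0201, adjusted p = 0.492 with an estimated correlation). With median-of-ratios scaling the p53 list had an adjusted p = 0.0566, within a range of 0.0107 to 0.492 over all alternatives. Gadd45a rose from 11.8 ± 1.42 TPM to 46.3 ± 4.40 TPM, and the death receptor Fas fell from 41.4 ± 3.58 TPM to 18.0 ± 0.218 TPM.

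Of 21 macrophage core genes, 20 fell (20 adjusted over the list alone, camera adjusted p = 1.38e-11, adjusted p = 0.00741 with an estimated correlation), and the other, Aif1, had a log2 fold change of -0.34. C1qa fell from 25.3 ± 4.92 TPM to 1.497 ± 0.664 TPM, C1qc from 52.1 ± 3.49 TPM to 4.91 ± 0.311 TPM, and Csf1r, the receptor for macrophage colony-stimulating factor, from 174 ± 15.4 TPM to 86.7 ± 10.4 TPM. Of 12 genes of alveolar macrophage identity, 10 fell (10 adjusted over the list alone, camera adjusted p = 2.18e-04, adjusted p = 0.0509 with an estimated correlation), and the others were Csf2ra and Il18. The fixed list held 22 genes, and those not tested had means over all libraries of at most 0.768 TPM. The fall therefore covers only the part of the list that these cells expressed. Marco (ENSMUSG00000026390), a scavenger receptor for particles and bacteria, fell from 789 ± 28.1 TPM to 195 ± 15.8 TPM, and the chitinase-like Chil3 from 364 ± 20.0 TPM to 109.9 ± 1.01 TPM. Of 11 LXR targets and lipid-efflux genes, 8 fell (9 adjusted over the list alone, camera adjusted p = 0.00557, adjusted p = 0.173 with an estimated correlation). Among them were the cholesterol exporter Abca1, from 22.9 ± 3.52 TPM to 13.8 ± 1.33 TPM, and Nr1h3, which encodes LXRα, from 16.3 ± 0.725 TPM to 9.66 ± 0.553 TPM. Of 33 interferon-stimulated genes, 21 fell and 4 rose, Bst2, Irf7, Isg15 and Ifit2 (21 and 5 adjusted over the list alone, camera adjusted p = 0.0307, adjusted p = 0.492 with an estimated correlation). That list had an adjusted p = 0.0658 without CuO NPs replicate 2 and 0.145 with the filter at 5 TPM, within a range of 8.64e-04 to 0.492 over all alternatives. Of 36 inflammatory and NF-kB genes, 19 fell and 7 rose (20 and 8 adjusted over the list alone, camera adjusted p = 0.275). Ccl7, a chemokine for monocytes, fell from 368 ± 2.89 TPM to 32.5 ± 1.22 TPM, and the granulocyte growth factor Csf3 from 35.4 ± 0.807 TPM to 5.0 ± 0.522 TPM. Cxcl2, a chemokine for neutrophils, rose from 179 ± 13.1 TPM to 342 ± 7.19 TPM. Of 42 lysosomal genes, 23 fell and 9 rose (24 and 9 adjusted over the list alone, camera adjusted p = 0.265), while 13 fell and 13 rose with median-of-ratios scaling, and the cathepsin Ctsb fell from 774 ± 42.0 TPM to 398 ± 11.8 TPM. With no filter the lysosomal list had an adjusted p = 0.0123, within a range of 0.0123 to 0.823 over all alternatives.

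Of 23 genes of the tricarboxylic acid cycle, 17 fell and 1 rose, the pyruvate carboxylase Pcx (17 and 1 adjusted over the list alone, camera adjusted p = 0.00413, adjusted p = 0.194 with an estimated correlation). Their median log2 fold change was -0.24, or -0.11 relative to the median of all genes, and 7 fell with median-of-ratios scaling, where the list had an adjusted p = 0.107 within a range of 8.90e-07 to 0.194 over all alternatives. Mdh1, the cytosolic malate dehydrogenase, fell from 191 ± 7.66 TPM to 126 ± 12.5 TPM. Of 31 glycolytic genes and HIF-1 targets, 20 fell and 4 rose, Vegfa, Ddit4, P4ha2 and Slc2a1 (20 and 4 adjusted over the list alone, camera adjusted p = 0.0123, adjusted p = 0.293 with an estimated correlation). With median-of-ratios scaling 14 of them fell, with an adjusted p = 0.0678 within a range of 9.11e-05 to 0.293 over all alternatives. Pdk1, which inhibits pyruvate dehydrogenase, fell from 17.4 ± 1.44 TPM to 6.22 ± 1.40 TPM. Of the 13 mitochondrially encoded mRNAs, 4 rose, mt-Nd4l, mt-Atp8, mt-Co1 and mt-Atp6 (3 adjusted over the list alone, camera adjusted p = 0.00436, adjusted p = 0.173 with an estimated correlation). With median-of-ratios scaling 7 rose, these 4 and mt-Nd3, mt-Co2 and mt-Nd4. With TPM scaling and the TPM of the nuclear copies added 6 rose, the same 4 and mt-Co2 and mt-Co3. Predicted nuclear genes repeat the sequences of mt-Nd4l, mt-Co1 and mt-Atp6, and the call of mt-Nd4l was lost without control replicate 3 (log2 fold change 0.34), CuO NPs replicate 1 (0.32) or CuO NPs replicate 3 (0.39). The mitochondrial list lost its call with quantile normalization (adjusted p = 0.413), where mt-Atp8 had a log2 fold change of 0.00. Quantile normalization gives the gene of highest level the same value in every library. In these groups that gene was mt-Atp8, at 68768 to 97125 TPM, so its change was fixed there and this setting could not measure it. Of 26 genes of ferroptosis and iron handling, 8 rose and 11 fell (8 and 12 adjusted over the list alone, camera adjusted p = 0.270), with a median of -0.06, a mean of 0.09, a positive sign of the test and a median above 0 under 3 of 5 other scalings. Of 21 immediate early genes, 6 rose and 10 fell (6 and 10 adjusted over the list alone, camera adjusted p = 0.825), with a median of -0.27 and a mean of -0.21 against a positive sign of the test, and the transcription factor Klf2 fell from 23.5 ± 1.69 TPM to 9.03 ± 1.05 TPM. Of 50 genes of DNA replication and mitosis, 22 rose and 22 fell (22 and 22 adjusted over the list alone, camera adjusted p = 0.0563), with a median of 0.09, a mean of -0.04 and a positive sign of the test. That list had an adjusted p = 0.0273 without CuO NPs replicate 2, within a range of 0.0273 to 0.492 over all alternatives, the highest with an estimated correlation. The mitotic kinase Plk1 fell from 103 ± 3.18 TPM to 38.1 ± 0.297 TPM.

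Of the 4 tested granulocyte and mast cell markers, Ly6g rose with 1.53, and S100a8 with -0.80, Cxcr2 with -0.84 and S100a9 with -1.73 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.270). That list had an adjusted p = 0.00785 without CuO NPs replicate 1, 0.0263 without CuO NPs replicate 2 and 0.0104 without CuO NPs replicate 3, within a range of 0.00785 to 0.492 over all alternatives, the highest with an estimated correlation. Ly6g reached 1 TPM only in the 3 CuO NP libraries (2.37 to 3.06 TPM). Leaving out any of these took Ly6g out through the filter and left the 3 markers that fell, so these gained calls were fixed by the filter. None of the 10 epithelial markers was tested, and the highest value of any of them was 0.590 TPM. Postn, the 1 tested fibroblast marker, fell from 14.7 ± 0.975 TPM to 2.74 ± 0.361 TPM (also adjusted over the list alone), and the endothelial marker Vwf had 9.98 ± 2.10 TPM and 10.1 ± 0.854 TPM. The lymphocyte marker Cd3e had 0.607 ± 0.117 TPM and 0.207 ± 0.090 TPM, and its fall was not called over all genes. It passed over the list alone, where Cd3e was the 1 tested member, so that p was not adjusted. All libraries of these groups were below 1 TPM, and Cd3e met the filter only through the TTM libraries (1.60 to 2.27 TPM).

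In all, limma called 5408 of 12904 genes, 1518 higher and 3890 lower, and 552 of them changed at least 2-fold, 162 higher and 390 lower. The 3 libraries of each group did not overlap for 53% of genes, where chance gives 10%. The median gene had a log2 fold change of -0.12, and with median-of-ratios scaling, which moves it to 0, 2574 genes were higher and 2555 lower, so the balance of directions depends on the scaling. Mitochondrially encoded mRNAs took 12.9 ± 0.467% of TPM in controls and 15.9 ± 0.211% with CuO NPs. The larger part of that rise was in 1 of them, mt-Atp8, from 71973 ± 3385 TPM to 95084 ± 1805 TPM. Of the 13 mRNAs, 4 were called higher and 9 were not called, so the larger share was no general rise.

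**Figure D1:**
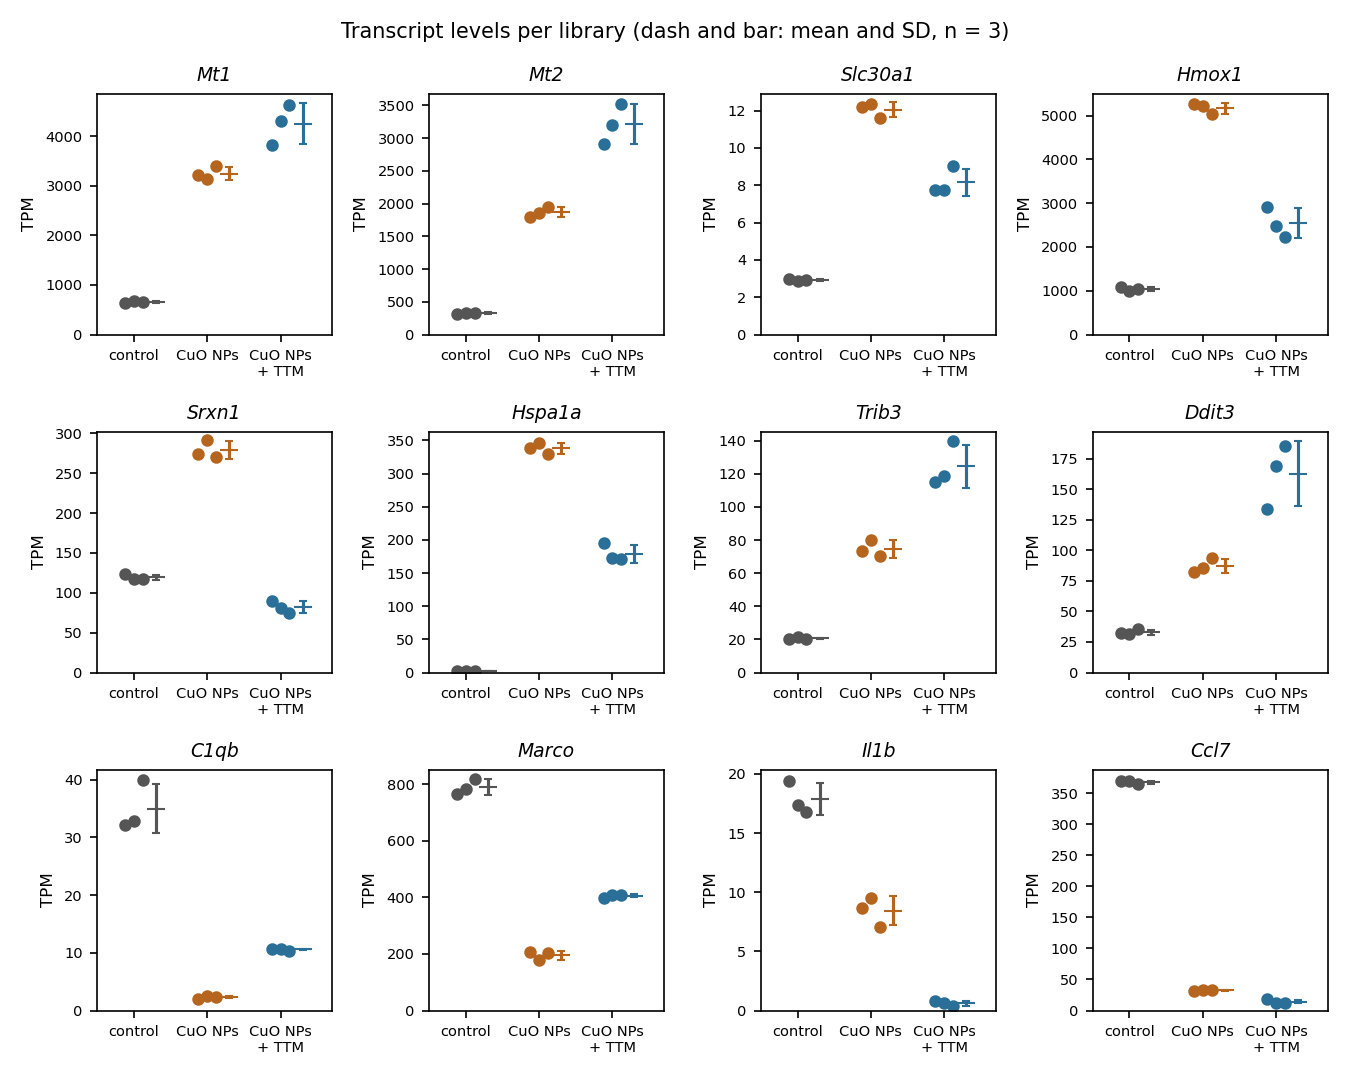
Levels of 12 genes in TPM (linear axis) in each of the 9 libraries, by group, with the dash and bar as mean ± SD (n = 3). Mt2 reached 1869 TPM with CuO NPs and 3213 TPM with TTM added, while Hmox1 reached 5165 TPM and 2544 TPM.

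Comparing CuO NPs + TTM with CuO NPs alone asked what TTM changed in the presence of the nanoparticles. Most NRF2 targets, heat shock factor 1 targets, proteasome subunits, ribosome biogenesis genes and inflammatory genes were lower with TTM, and most genes of cholesterol synthesis and the tricarboxylic acid cycle were higher. Camera called 15 of 30 lists here, and 0 with an estimated correlation, where 6 had an unadjusted p below the threshold. Srxn1 (ENSMUSG00000032802), which encodes an enzyme that restores oxidised peroxiredoxins, fell from 279 ± 11.1 TPM to 82.0 ± 7.92 TPM, below its 119 ± 3.51 TPM in controls. Hmox1 fell from 5165 ± 124 TPM to 2544 ± 350 TPM. The metallothioneins went the other way, with Mt1 at 4255 ± 404 TPM after 3243 ± 133 TPM and Mt2 at 3213 ± 303 TPM after 1869 ± 74.1 TPM.

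Among the 4 tested metallothionein and zinc-export genes, 2 rose, Mt2 with a log2 fold change of 0.78 (SE 0.065) and Mt1 with 0.39 (SE 0.067), and 2 fell, Slc30a1 with -0.51 and Mtf1 with -0.61 (2 and 2 adjusted over the list alone, camera adjusted p = 0.847). Mt1 lost its call when each library was centred on its median gene (log2 fold change 0.20, limma adjusted p = 0.0975). The median of the list was -0.06, its mean 0.01 and the sign of its test negative, and the median was above 0 under 2 of 5 other scalings. Among 17 copper-handling genes, 6 rose and 2 fell, Sod1 with -0.21 and Sco2 with -1.03 (6 and 2 adjusted over the list alone, camera adjusted p = 0.870), with a mean of 0.09 against a negative sign of the test, and their median of 0.00 was below 0 under all 5 other scalings. With median-of-ratios scaling 5 rose, Cp, Atp7a, Steap1, Steap3 and Slc31a1, and 4 fell, Cox19, Sod1, Atox1 and Sco2. Atp7a rose from 9.94 ± 1.39 TPM to 15.5 ± 0.506 TPM and Slc31a1 from 46.7 ± 1.51 TPM to 60.7 ± 2.57 TPM. Among 18 genes of cuproptosis and lipoylation, 12 rose and 3 fell, Gcsh, Lipt2 and Mtf1 (12 and 3 adjusted over the list alone, camera adjusted p = 0.0498, adjusted p = 0.472 with an estimated correlation). Dlat, the acetyltransferase subunit of pyruvate dehydrogenase, rose from 42.4 ± 0.996 TPM to 68.9 ± 8.16 TPM, and Fdx1 had a log2 fold change of 0.16. Lias, the lipoyl synthase, had 0.26 and lost its call without CuO NPs replicate 3 (0.24) and with median-of-ratios scaling (0.13).

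Of 37 NRF2 targets, 23 fell and 8 rose (24 and 8 adjusted over the list alone, camera adjusted p = 2.82e-08, adjusted p = 0.118 with an estimated correlation), and with median-of-ratios scaling 28 fell and 3 rose, Gstp1, Cbr3 and Cbr1. Gclm, a subunit of the enzyme that starts glutathione synthesis, fell from 309 ± 18.0 TPM to 117 ± 8.52 TPM, and Nqo1 from 5.06 ± 1.499 TPM to 1.10 ± 0.185 TPM. Of 25 heat shock factor 1 targets and chaperones, 17 fell and 2 rose, Hspa4l with 0.35 and Fkbp4 with 0.25 (17 and 2 adjusted over the list alone, camera adjusted p = 1.36e-07, adjusted p = 0.218 with an estimated correlation). Hspa1a fell from 338 ± 8.32 TPM to 179 ± 13.7 TPM and Hsph1 from 523 ± 28.3 TPM to 267 ± 19.3 TPM. Of 31 proteasome subunits, 27 fell and 1 rose, Psmd8 with 0.46 (27 and 1 adjusted over the list alone, camera adjusted p = 2.32e-11, adjusted p = 0.118 with an estimated correlation). Psmc4, an ATPase of the 19S particle, fell from 172 ± 15.5 TPM to 97.5 ± 1.84 TPM. Of 35 ribosome biogenesis genes, 31 fell (31 adjusted over the list alone, camera adjusted p = 2.28e-16, adjusted p = 0.118 with an estimated correlation), and the others were Polr1c, Wdr75, Nle1 and Polr1b. Tsr1, a factor of small-subunit assembly, fell from 71.2 ± 7.50 TPM to 26.9 ± 2.57 TPM and the snoRNP protein Nop58 from 363 ± 6.31 TPM to 169 ± 22.1 TPM.

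Of 36 inflammatory and NF-kB genes, 24 fell and 4 rose, Tnfaip3 with 0.74, Tnfaip2 with 0.69, Nos2 with 0.59 and Ccl9 with 0.44 (24 and 5 adjusted over the list alone, camera adjusted p = 3.74e-09, adjusted p = 0.118 with an estimated correlation). Il1b, which encodes interleukin 1β, fell from 8.42 ± 1.23 TPM to 0.620 ± 0.226 TPM, and Cxcl2 from 342 ± 7.19 TPM to 91.7 ± 23.8 TPM. Of the 4 tested granulocyte and mast cell markers, 3 fell, S100a8 with -1.58, Ly6g with -1.70 and S100a9 with -2.06 (3 adjusted over the list alone, camera adjusted p = 0.00485, adjusted p = 0.118 with an estimated correlation). S100a8, a calcium-binding alarmin, fell from 193 ± 8.45 TPM to 63.8 ± 3.57 TPM. Of 21 macrophage core genes, 14 rose and 4 fell, Fcgr3 with -0.36, Spi1 with -0.42, Cd14 with -0.51 and Csf1r with -0.95 (15 and 4 adjusted over the list alone, camera adjusted p = 0.0627), and with median-of-ratios scaling 9 rose and the same 4 fell. The macrophage core list had an adjusted p = 0.0189 with quantile normalization and 0.00266 with no filter, within a range of 0.00266 to 0.218 over all alternatives. C1qb rose from 2.28 ± 0.187 TPM to 10.6 ± 0.164 TPM and the β-glucan receptor Clec7a from 4.88 ± 1.17 TPM to 12.7 ± 1.51 TPM, both below their control levels of 35.0 ± 4.25 TPM and 21.0 ± 1.99 TPM. Of 12 genes of alveolar macrophage identity, 6 rose and 1 fell, Chil3 with -0.56 (6 and 1 adjusted over the list alone, camera adjusted p = 0.161). Marco rose from 195 ± 15.8 TPM to 405 ± 5.62 TPM and Fabp5 from 136 ± 9.25 TPM to 298 ± 7.98 TPM. Of 11 LXR targets, 5 rose, Abcg1, Scd2, Scd1, Srebf1 and Abca1, and 1 fell, Nr1h3 with -1.03 (6 and 1 adjusted over the list alone, camera adjusted p = 0.298).

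Of 23 cholesterol and SREBP2 genes, 21 rose (21 adjusted over the list alone, camera adjusted p = 8.52e-07, adjusted p = 0.218 with an estimated correlation), and the others were Hsd17b7 and Ebp. Mvd and Hmgcs1, enzymes of the mevalonate pathway, rose from 24.5 ± 0.483 TPM to 66.2 ± 11.3 TPM and from 29.7 ± 2.28 TPM to 67.2 ± 6.44 TPM. Of 23 genes of the tricarboxylic acid cycle, 20 rose (21 adjusted over the list alone, camera adjusted p = 1.36e-05, adjusted p = 0.118 with an estimated correlation), and the others were Sucla2, Suclg1 and Pcx. Idh2, the mitochondrial isocitrate dehydrogenase, rose from 114 ± 2.84 TPM to 189.8 ± 12.2 TPM. Of the 13 mitochondrially encoded mRNAs, 3 rose, mt-Nd6, mt-Nd5 and mt-Co1, and 5 fell, mt-Nd4, mt-Nd2, mt-Atp8, mt-Cytb and mt-Nd1 (3 and 5 adjusted over the list alone, camera adjusted p = 0.0631). With the TPM of the nuclear copies added, the same 3 rose and 9 fell, the further ones being mt-Nd3, mt-Nd4l, mt-Co3 and mt-Atp6. With median-of-ratios scaling the same 5 fell and none rose, with log2 fold changes of 0.15 for mt-Nd6, 0.11 for mt-Nd5 and 0.09 for mt-Co1, so these rises depend on the scaling. That list had an adjusted p = 0.0475 without CuO NPs replicate 2 and 0.0421 without CuO NPs + TTM replicate 1, within a range of 0.0421 to 0.400 over all alternatives, the highest with an estimated correlation. mt-Nd1 fell from 10584 ± 315 TPM to 5333 ± 903 TPM and mt-Cytb from 13686 ± 405 TPM to 7814 ± 637 TPM, while mt-Co1 was at 14084 ± 194 TPM and 16418 ± 1301 TPM.

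Besides cuproptosis, further lists passed with TPM scaling and not with median-of-ratios scaling. Among them were the integrated stress response with 20 up and 5 down, Sesn2, Atf3, Ppp1r15a, Slc3a2 and Slc7a11 (20 and 5 adjusted over the list alone, camera adjusted p = 0.0498, adjusted p = 0.590 with an estimated correlation), and antigen presentation with 6 up of 12 (6 adjusted over the list alone, camera adjusted p = 0.0413, adjusted p = 0.400 with an estimated correlation). Of 42 lysosomal genes, 22 rose and 5 fell, Atp6v0b, Atp6v1b2, Atp6v1h, Tfe3 and Atp6v1d (25 and 5 adjusted over the list alone, camera adjusted p = 0.00433, adjusted p = 0.400 with an estimated correlation). With median-of-ratios scaling 21 lysosomal genes rose and 11 fell, and of the integrated stress response 16 rose and 7 fell. Of 49 nuclear genes of the respiratory chain, 30 rose and 4 fell, Cox5b, Atp5mc1, Cycs and Atp5mc3 (30 and 4 adjusted over the list alone, camera adjusted p = 0.00721, adjusted p = 0.555 with an estimated correlation). With median-of-ratios scaling 13 of these rose and 5 fell, the same 4 and Cox6c. Of 21 immediate early genes, 10 fell and 3 rose, Myc, Zfp36 and Nr4a1 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0319, adjusted p = 0.472 with an estimated correlation). The median-of-ratios adjusted p-values were 0.0955 for cuproptosis, 0.169 for the integrated stress response, 0.105 for antigen presentation, 0.102 for the lysosome, 0.209 for the respiratory chain and 0.0955 for immediate early genes. Over all alternatives the ranges were 0.00222 to 0.472, 0.00118 to 0.590, 9.68e-04 to 0.400, 2.38e-06 to 0.400, 5.20e-06 to 0.555 and 0.0170 to 0.472 in the same order. Without 1 library the cuproptosis list had adjusted p-values of 0.0607 (control replicate 1), 0.0539 (CuO NPs replicate 1), 0.0761 (CuO NPs replicate 2), 0.0547 (CuO NPs + TTM replicate 2) and 0.0517 (CuO NPs + TTM replicate 3). The integrated stress response list had 0.0607 (control replicate 1), 0.0504 (control replicate 3), 0.0558 (CuO NPs replicate 1), 0.0539 (CuO NPs replicate 2), 0.0569 (CuO NPs replicate 3) and 0.0733 (CuO NPs + TTM replicate 3), and antigen presentation had 0.0539 (CuO NPs replicate 1), 0.0591 (CuO NPs replicate 2) and 0.0517 (CuO NPs + TTM replicate 3). The respiratory chain had 0.0515 without CuO NPs replicate 2, and immediate early genes had 0.0547 without CuO NPs + TTM replicate 2. Among single members, Trib3 rose from 74.6 ± 5.19 TPM to 124 ± 13.3 TPM, Aldh18a1, an enzyme of proline synthesis, from 51.7 ± 4.78 TPM to 122 ± 6.05 TPM, and the lysosomal glycoprotein Gpnmb from 966 ± 21.0 TPM to 1937 ± 48.2 TPM.

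Altogether limma called 6853 of 12904 genes, 4469 higher and 2384 lower with TTM, and 763 changed at least 2-fold, 532 higher and 231 lower. The groups did not overlap for 59.4% of genes, where chance gives 10%. The median gene had a log2 fold change of 0.12, and with median-of-ratios scaling 3394 genes were higher and 3515 lower. The share of mitochondrially encoded mRNAs was 15.9 ± 0.211% of TPM with CuO NPs and 12.3 ± 1.05% with TTM added. The larger part of that fall was in mt-Atp8, from 95084 ± 1805 TPM to 71905 ± 8811 TPM.

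**Figure D2:**
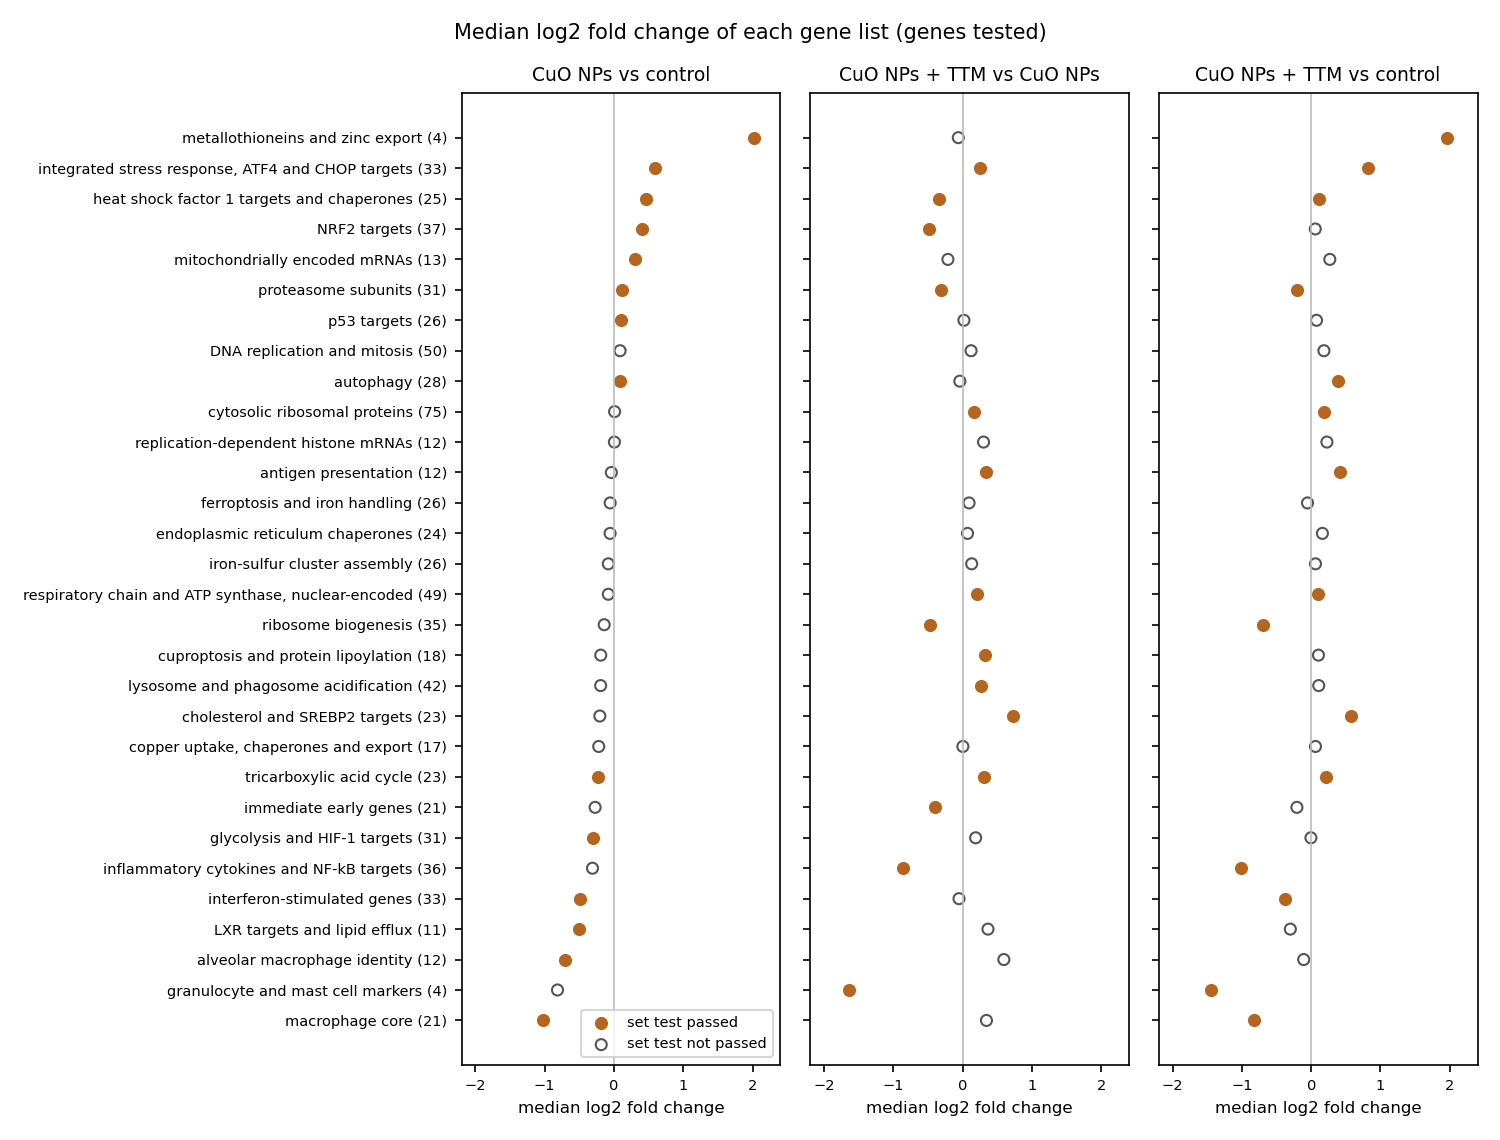
Median log2 fold change of the tested members of 30 fixed gene lists in the 3 comparisons, with filled marks where the set test passed with a preset correlation. Macrophage core genes had medians of -1.03 with CuO NPs against control and -0.82 with CuO NPs + TTM against control, and with an estimated correlation these 2 were the calls that held.

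CuO NPs + TTM against control asked what difference from control was left with both. Most genes of the metallothionein and integrated stress response lists were above control, and most inflammatory, ribosome biogenesis and macrophage core genes were below it. Camera called 15 of 30 lists, and with an estimated correlation the macrophage core genes were again the only list called. Mt2 rose from 328 ± 10.5 TPM to 3213 ± 303 TPM, with a log2 fold change of 3.29 (SE 0.065), and Hspa1a from 2.36 ± 0.426 TPM to 179 ± 13.7 TPM. Ddit3 (ENSMUSG00000025408) rose from 33.0 ± 2.10 TPM to 163 ± 26.6 TPM. Ccl2 (ENSMUSG00000035385), a chemokine for monocytes, fell from 856 ± 43.5 TPM to 56.0 ± 18.1 TPM, and Ccl7 from 368 ± 2.89 TPM to 14.4 ± 3.08 TPM.

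Of the 4 metallothionein and zinc-export genes, 3 rose, Mt2, Mt1 and Slc30a1, and Mtf1 fell with -0.59 (3 and 1 adjusted over the list alone, camera adjusted p = 0.0175, adjusted p = 0.344 with an estimated correlation). Of 33 targets of the integrated stress response, 28 rose and 2 fell, Slc3a2 with -0.13 and Atf5 with -0.90 (30 and 2 adjusted over the list alone, camera adjusted p = 3.05e-12, adjusted p = 0.218 with an estimated correlation). Of 25 heat shock factor 1 targets and chaperones, 11 rose and 6 fell (12 and 6 adjusted over the list alone, camera adjusted p = 0.0354, adjusted p = 0.661 with an estimated correlation), with an adjusted p = 0.0552 without control replicate 2 and a range of 0.00161 to 0.661 over all alternatives. Of 37 NRF2 targets, 15 rose and 10 fell (16 and 10 adjusted over the list alone, camera adjusted p = 0.268). Osgin1, a growth inhibitor induced by oxidative stress, fell from 34.1 ± 3.36 TPM to 10.7 ± 2.10 TPM. Of 24 chaperones of the endoplasmic reticulum, 11 rose and 7 fell (11 and 7 adjusted over the list alone, camera adjusted p = 0.194, or 0.0172 with quantile normalization within a range of 0.0172 to 0.678 over all alternatives), and Sdf2l1 rose from 48.1 ± 4.68 TPM to 96.2 ± 8.41 TPM. Of 28 autophagy genes, 16 rose and 4 fell, Atg5, Atg13, Tax1bp1 and Atg3 (17 and 4 adjusted over the list alone, camera adjusted p = 0.00912, adjusted p = 0.237 with an estimated correlation). Ulk1, a kinase that starts autophagy, rose from 9.05 ± 0.215 TPM to 28.6 ± 1.57 TPM. Of 12 antigen presentation genes, 8 rose (8 adjusted over the list alone, camera adjusted p = 0.00431, adjusted p = 0.237 with an estimated correlation), and the others were Nlrc5, Cd74, Psmb10 and H2-DMa. H2-D1, a class I molecule, rose from 183.5 ± 9.34 TPM to 374 ± 29.1 TPM. Of 23 cholesterol and SREBP2 genes, 18 rose and 1 fell, Hsd17b7 with -0.60 (18 and 1 adjusted over the list alone, camera adjusted p = 6.12e-05, adjusted p = 0.344 with an estimated correlation), and Insig1 rose from 67.4 ± 3.89 TPM to 180.1 ± 28.4 TPM. Of 23 genes of the tricarboxylic acid cycle, 14 rose and 2 fell, Idh3a and Sucla2 (14 and 3 adjusted over the list alone, camera adjusted p = 0.0175, adjusted p = 0.344 with an estimated correlation). Of 75 cytosolic ribosomal proteins, 41 rose and 6 fell (41 and 7 adjusted over the list alone, camera adjusted p = 1.03e-04, adjusted p = 0.661 with an estimated correlation), and Rplp1 rose from 2311 ± 161 TPM to 3392 ± 297 TPM. Of 49 nuclear genes of the respiratory chain, 20 rose and 8 fell (21 and 8 adjusted over the list alone, camera adjusted p = 0.0354, adjusted p = 0.668 with an estimated correlation). That list had an adjusted p = 0.0557 with median-of-ratios scaling, 0.0759 without control replicate 1, 0.0620 without control replicate 3 and 0.0998 without CuO NPs + TTM replicate 2, within a range of 1.41e-04 to 0.668 over all alternatives.

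Of 36 inflammatory and NF-kB genes, 27 fell and 5 rose, Saa3, Tnfaip2, Relb, Nos2 and Nfkb2 (27 and 5 adjusted over the list alone, camera adjusted p = 8.24e-07, adjusted p = 0.218 with an estimated correlation). Csf3 fell from 35.4 ± 0.807 TPM to 0.777 ± 0.015 TPM and Il1b from 17.9 ± 1.38 TPM to 0.620 ± 0.226 TPM. Of 33 interferon-stimulated genes, 19 fell and 4 rose, Bst2, Irf7, Ifit2 and Stat2 (20 and 4 adjusted over the list alone, camera adjusted p = 0.00452, adjusted p = 0.402 with an estimated correlation), and Rtp4 fell from 43.0 ± 1.80 TPM to 12.7 ± 1.14 TPM. Of 35 ribosome biogenesis genes, 32 fell (32 adjusted over the list alone, camera adjusted p = 1.25e-11, adjusted p = 0.218 with an estimated correlation), and the others were Polr1c, Nop14 and Wdr75. Rrp12, a factor of ribosome export, fell from 53.2 ± 1.38 TPM to 18.5 ± 2.46 TPM. Of 31 proteasome subunits, 17 fell and 4 rose, Psmd8, Psmb3, Psmb6 and Psmd4 (17 and 4 adjusted over the list alone, camera adjusted p = 0.0241, adjusted p = 0.661 with an estimated correlation). That list had an adjusted p = 0.0525 without control replicate 2 and 0.559 with quantile normalization, within a range of 0.00161 to 0.661 over all alternatives. Of 21 macrophage core genes, 14 fell and 2 rose, Fcgr2b and Trem2 (16 and 2 adjusted over the list alone, camera adjusted p = 2.69e-06, adjusted p = 0.0423 with an estimated correlation). Csf1r fell from 174 ± 15.4 TPM to 44.4 ± 6.44 TPM. Of 12 genes of alveolar macrophage identity, 3 rose, Bhlhe41, Fabp5 and Itgax, and 5 fell, Cd9, Marco, Csf2rb, Plet1 and Chil3 (3 and 5 adjusted over the list alone, camera adjusted p = 0.392), with a median of -0.11 that was 0.02 under 1 of 5 other scalings. Of the 4 granulocyte and mast cell markers, 3 fell, Cxcr2, S100a8 and S100a9 (3 adjusted over the list alone, camera adjusted p = 0.0136, adjusted p = 0.218 with an estimated correlation). S100a9 fell from 55.2 ± 3.47 TPM to 3.08 ± 0.255 TPM, and Cxcr2, with -0.52, lost its call without control replicate 3 (-0.48) or CuO NPs + TTM replicate 3 (-0.39). Of 26 iron-sulfur cluster assembly genes, 7 rose and 7 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.676), and Hscb rose from 28.7 ± 1.60 TPM to 91.2 ± 9.86 TPM. Of the 12 replication-dependent histone genes, 3 rose, H3c3, H2ac8 and H2bc4 (2 adjusted over the list alone, camera adjusted p = 0.431), and poly(A) selection leaves most histone mRNAs out. H2bc4, with 0.39, kept its call without CuO NPs replicates 2 and 3 and CuO NPs + TTM replicate 1, and lost it without each of the other 6 libraries (0.25 to 0.44). Cd3e rose from 0.607 ± 0.117 TPM to 1.99 ± 0.350 TPM, and Postn was at 2.80 ± 0.818 TPM.

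In this comparison limma called 7164 of 12904 genes, 3526 higher and 3638 lower, and 981 changed at least 2-fold, 456 higher and 525 lower. The groups did not overlap for 63.1% of genes, where chance gives 10%, and the median gene had a log2 fold change of 0.00.

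The reversal of CuO NP changes asked how much of the nanoparticle response was left with TTM. Of the 5408 genes called with CuO NPs, 2407 (44.5%) were called in the opposite direction with TTM, 942 (17.4%) were called further in the same direction, and 2059 were not called between the nanoparticle groups. The median gene kept 0.632 of its CuO NP change with TTM, and the 3 TTM libraries taken singly gave 0.631 ± 0.037 (SD, n = 3). Both differences in this share use the control libraries, and simulated unchanged groups gave 0.499 on average and between 0.477 and 0.516. With 1 control library for the numerator and the other 2 for the calls and the denominator, the share was 0.585 ± 0.055 (SD over the 3 choices, 0.536 to 0.644), so its size is uncertain, as are those of the lists. Single genes spread widely around that median. With TTM, 2298 of the 5408 genes lay between control and the CuO NP level, 1789 beyond the CuO NP level and 1321 past control. Genes at least 2-fold higher with CuO NPs kept a median of 0.513, and those at least 2-fold lower 0.731. NRF2 targets kept a median of 0.235, with 22 of 30 called genes opposite, and proteasome subunits 0.193, with 14 of 17 opposite. Heat shock factor 1 targets kept 0.638, with 15 of 20 opposite, and macrophage core genes 0.603, with 14 of 20 opposite. Genes of the integrated stress response had a median of 1.36, with 16 of 28 called in the same direction again. Lysosomal genes kept 0.048, with 21 of 32 opposite, and genes of the tricarboxylic acid cycle passed beyond control with -0.40, with 15 of 18 opposite, although the changes of these 2 lists with CuO NPs depended on the scaling, as did the further change of the integrated stress response list with TTM. Differences between lists in these shares were not tested.

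Both comparisons used the CuO NP libraries, which alone makes their fold changes run opposite. Across genes the covariance of the fold changes was -0.0975, where simulated unchanged groups with shared libraries gave -0.0250 on average and between -0.0326 and -0.0169, a difference of -0.0725. The correlation across genes was -0.351, against -0.507 in the simulations. Lists of called genes drawn independently would share 280 genes higher and then lower and 1347 lower and then higher, where 568 and 1839 were found. Part of that excess may come from the shared libraries, since 3 libraries do not divide into groups with replicates.

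**Figure D3:**
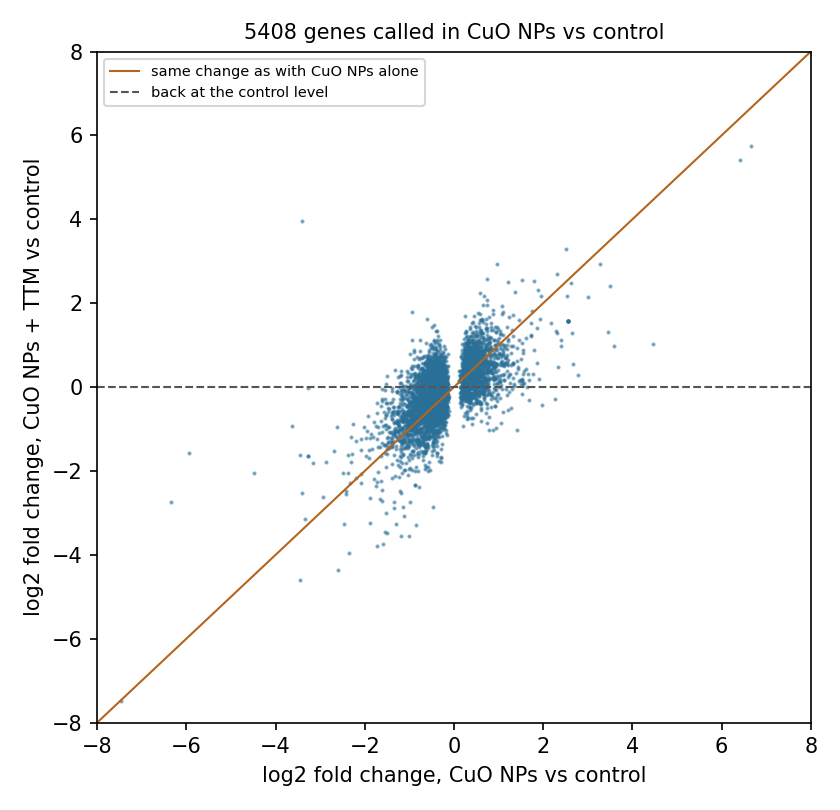
Log2 fold change against control of 5408 genes called with CuO NPs, without TTM on the x axis and with TTM on the y axis, with a solid line for the same change and a dashed line for the control level. The median gene kept 0.632 of its change, and 2407 genes were called in the opposite direction between the nanoparticle groups.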

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

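The scaling without mitochondrial genes, their copies and ferritin and the centring on the median gene were chosen after the data were seen, and the other alternatives before. Over 22 alternatives other than the estimated correlation, no result for a named gene or a fixed list that had passed its test turned to the opposite direction past it. Of 6830 values for 314 results on named genes, 6723 stayed on their side of the threshold, 99 lost the call and 8 gained it. Of 1971 values for the 90 list results, 1869 stayed, 72 lost the call and 30 gained it.

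The camera test called 14, 15 and 15 of 30 lists for CuO NPs against control, CuO NPs + TTM against CuO NPs, and CuO NPs + TTM against control. With an estimated correlation it called 1, 0 and 1, where 8, 6 and 5 lists had an unadjusted p below the threshold. For CuO NPs + TTM against CuO NPs, 8 lists were called with median-of-ratios scaling and 8 with libraries centred on the median gene. The setting with an estimated correlation also uses fewer degrees of freedom, which raises p at the same correlation. How much of each drop came from this was not tested, nor was the cause of the drops under the other scalings. For CuO NPs against control, alveolar macrophage identity had an estimated correlation of 0.0106, near the preset 0.01. Its unadjusted camera p still went from 5.08e-05 to 0.00679. Macrophage core genes, with an estimate of -0.0289, went from 1.84e-12 to 2.47e-04. For these lists a higher correlation was therefore not the cause of the larger p. With 1 library left out, the called lists ranged over 14 to 16, 11 to 16 and 13 to 16.

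Leaving out 1 library at a time gave 4395 to 5442 changed genes for CuO NPs against control, 6035 to 6702 for CuO NPs + TTM against CuO NPs and 6283 to 7266 for CuO NPs + TTM against control. The genes called in the opposite direction with TTM ranged over 1906 to 2323, and the median share of the CuO NP change left over 0.594 to 0.660. That share was 0.713 with quantile normalization. With no filter, 28033 genes were tested and 4786, 6471 and 6826 were called. Of the genes called with TPM scaling, median-of-ratios scaling kept 4072 of 5408, 5776 of 6853 and 6983 of 7164, and turned none of them that it called. The balance of directions moved to 3134 higher and 2071 lower for CuO NPs against control and 2741 higher and 4222 lower for CuO NPs + TTM against CuO NPs with libraries centred on the median gene. Counts of genes changed at least 2-fold depended on the pseudocount, which acts on genes with few TPM. They were 833, 1266 and 1451 with a pseudocount of 0.1, and 242, 212 and 386 with 5.

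The replicate numbers are not said to mark a shared culture or day. Deviations from group means correlated across genes by -0.127 to 0.010 between libraries of the same number, and with the number as a block 4925, 6469 and 6798 genes were called. The depth of the libraries is unknown, so no limit from counting could be given.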

Other observations

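The division of the cell-cycle list and the tests of explanations for the balance of directions, the mitochondrial mRNAs and the metallothioneins were chosen after the results were seen (as were the members named for their small counts), and the count over other splits of the libraries was chosen before.

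The fixed list of DNA replication and mitosis genes held members that moved apart with CuO NPs. Of its 23 mitotic genes 21 fell, with a median log2 fold change of -0.73, and of its 27 replication genes 22 rose and 1 fell, Ccne1 with -0.23, with a median of 0.66 (limma). A permutation test of ranks between the parts gave p = 1e-05 (100000 permutations). The division was made after members were seen to move both ways and genes are not independent, so this p is no evidence for the difference. With median-of-ratios scaling the medians were -0.60 and 0.80. Ccnb1, the cyclin that drives entry into mitosis, fell from 143 ± 5.41 TPM to 60.5 ± 1.87 TPM (SD, n = 3), and Cdc45, a part of the replicative helicase, rose from 40.6 ± 0.307 TPM to 79.4 ± 1.55 TPM. With TTM added, 14 of the mitotic genes rose and 2 fell against CuO NPs alone, Kif20a with -0.33 and Kif23 with -0.40, with a median of 0.27. Of the replication genes 7 rose and 7 fell, with a median of -0.07. With median-of-ratios scaling 11 mitotic genes rose and 4 fell, Birc5, Kif11, Kif20a and Kif23, with a median of 0.14, while 1 replication gene rose, Cdc45, and 14 fell, with a median of -0.20. Aurkb, a kinase of chromosome segregation, rose from 49.96 ± 1.49 TPM to 98.7 ± 4.21 TPM, while Kif20a, a kinesin of cytokinesis, was at 53.7 ± 0.896 TPM with CuO NPs and 42.5 ± 2.72 TPM with TTM. Against control, the medians with TTM were -0.38 for mitosis and 0.53 for replication.

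Several of the genes with the largest changes between the nanoparticle groups were on no fixed list. Lower with TTM were the formyl peptide receptor Fpr2, from 23.1 ± 1.18 TPM to 3.65 ± 1.64 TPM (SD, n = 3), the amplifying receptor Trem1, from 7.85 ± 0.324 TPM to 0.717 ± 0.404 TPM, and the fatty acid receptor Gpr84, from 6.16 ± 0.220 TPM to 0.410 ± 0.260 TPM. Il1f9, which encodes interleukin 36γ, rose with CuO NPs from 10.97 ± 1.44 TPM to 30.6 ± 1.66 TPM and was at 4.89 ± 0.474 TPM with TTM. The channel gene Pkd2l1 was higher with TTM, at 179 ± 10.0 TPM after 37.5 ± 1.85 TPM, as were Rufy4, at 26.9 ± 3.16 TPM after 4.79 ± 0.230 TPM, and the clock repressor Nr1d1, at 20.9 ± 4.85 TPM after 4.44 ± 0.569 TPM. The small nucleolar RNA Snord22 had 196 ± 95.9 TPM in controls (92.0 to 281 TPM) and was listed at 0 in all 6 libraries with CuO NPs. Another, Snora65, had 0 to 49.3 TPM in controls, 0 with CuO NPs alone and 164 ± 17.5 TPM with TTM. Levels of both varied widely between control libraries, so their values are uncertain. Exosc6 was listed at 0 in the 3 libraries with TTM. The pseudogenes Rpl35a-ps4, Rps12-ps3, Rps13-ps2 and Mpc1-ps were among the largest changes against control and share sequence with their parent genes, so their values are uncertain.

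Each comparison of 3 with 3 libraries allows 10 splits, which are too few for a share under 0.05, and 1 of the 10, the real one, gave as many called genes in each. The real splits gave 5408, 6853 and 7164 called genes and the highest of the others gave 2, 2 and 2. Every other split mixes libraries of both groups, which puts their difference into the spread. Those low counts therefore do not measure how many genes unchanged groups would give.

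More genes were lower than higher with CuO NPs (3890 and 1518). TPM values add to a fixed total, and mitochondrial transcripts, the predicted genes that repeat them and ferritin took 24.2 ± 0.540% of it in controls and 29.4 ± 0.374% with CuO NPs (SD, n = 3). With those genes left out of the total, the median gene moved from -0.12 to -0.038 (log2), where their shares alone would put it at -0.10. The larger share of these transcripts may therefore account for most of the surplus of lower genes, although 2199 were then higher and 2805 lower. Whether the RNA content of the cells differed stays open, since TPM holds no absolute level.

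Among mitochondrially encoded mRNAs, mt-Nd1 and mt-Cytb fell with TTM against CuO NPs alone while mt-Co1 did not, and the rise of mt-Co1 in TPM (log2 0.22) was 0.09 with median-of-ratios scaling and no longer called. Reads shared with predicted nuclear genes that repeat mitochondrial mRNAs were tested by adding the TPM of each copy to that of its parent. The change in log2 mt-Nd1 over mt-Co1 was then -1.23 (SE 0.234), against -1.22 without the copies. A lower yield of all mitochondrial mRNAs would move the 13 alike, but their changes had an SD of 0.396, above 0.159, the highest of 10000 simulations with 1 common change. These values argue against both as the whole cause, and an effect of TTM on single mitochondrial mRNAs may remain as an untested explanation, as may a difference in their poly(A) tails at selection.

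Mt1 and Mt2 rose further with TTM while Hmox1 fell. A shift in the TPM total would move them alike, and with median-of-ratios scaling the lower of the Mt1 and Mt2 changes was 0.257 (SE 0.093) while that of Hmox1 was -1.16. With libraries centred on the median gene Mt1 had 0.20 and lost its call, so the argument for Mt1 is weaker than for Mt2. If TTM lowered the whole response to the nanoparticles, both would fall, and their mean change was 0.583 (SE 0.085), but Slc30a1 on the same list fell with -0.51 (SE 0.086) and Mtf1 with -0.61, or -0.63 and -0.73 with median-of-ratios scaling. Why these genes moved apart stays open, and without a group given TTM alone so does an effect of TTM by itself on the metallothioneins.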
